A study of Arabidopsis thaliana with 20 samples.

How the data were processed

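The study covers 20 samples of whole seedlings from a line that carries HSFA1d fused to GFP, 10 precipitated with an antibody against GFP and 10 of input chromatin. Per the labels' protocols, nuclei were isolated from seedlings cross-linked with formaldehyde, chromatin was sheared by sonication, and libraries were read as single reads of 50 bases. Per the submitters' processing notes the tools were Bowtie2, SAMtools and MACS2 and the genome build was TAIR10; versions are not given in the sources used here. Per the labels, fastq files were concatenated, so each condition has 1 list of peaks from pooled reads: 3 ChIP samples in HT0 and HS, and 1 in WT0, W10min, W3h and W24h. No filter on q is stated in the sources used here, and 16.4% of HT0 peaks and 7.4% of W10min peaks have a q of 1. The labels give a floor of 10 M mapped reads for each library, and totals per library are unknown, so no interval or detection limit that needs depth is given.

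The fold enrichment of each peak is a ratio that the authors deposited, per the file headers, and the significance of each peak is a −log10 q that the authors deposited, per the file headers. Rows also carry a gene identifier, an annotation class (promoter, gene, transposable element gene and others) and a strand. Promoter rows are up to 3001 bp wide. Starts were found to count from 0, since they equal gene starts of the reference far more often after adding 1 (115 against 2 rows in HT0), and 1 was added. Parts of a peak outside annotated features are not listed, and the annotation step had split peaks over rows. Rows of 1 list with the same fold and q that overlapped or had at most 1 base between them were joined, which gave 1336 peaks from 1967 rows in HT0 and 2103 from 3848 in HS.

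Gene symbols and the background of 27444 nuclear protein-coding genes came from a RefSeq table of assembly TAIR10.1, used for names and not for coordinates. Between 6 identifiers (W24h) and 41 (W10min) per list were not in that table. Common names of listed genes (WIND1, PLT3, PLT7, ERF109, HSP90.2) are used in place of RefSeq symbols. A gene had a peak when any row of any listed peak named it, in the promoter or the gene. It was gained when it had a peak in the treated list and none in the matched time 0 list, HT0 for heat and WT0 for wounding.

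Peaks met when they overlapped by at least 1 bp. The share was set against 1000 placements of the first list at random positions on the same chromosomes (seeded), a one-sided permutation test. Random positions include unannotated sequence where no peak could be listed, so the random share is low by construction. The 14 gene lists, 265 genes in all, were set before the data were examined. Each was tested in each of the 6 peak lists against other coding genes (84 tests) and among gained genes against genes free of a peak at time 0 (56 tests), by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over each family and a threshold of 0.05. Genes are not replicates, neighbouring genes can share a peak, and a p compares deposited lists, not conditions. Exact McNemar tests of the members of a list between 2 peak lists, adjusted over 15 groups for each pair, were chosen after seeing the data. The lists were small heat shock proteins, the HSP70 family, HSP90 with HSP100 and HSP60, co-chaperones, heat shock factors, other heat and oxidative stress genes, endoplasmic reticulum folding with polyubiquitin, reprogramming regulators, early wound and touch genes, jasmonate, auxin with cytokinin, cell cycle, photosynthesis and reference genes.

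Genes named in the text were chosen by a rule set before the data were examined. It takes the 10 genes with the highest fold among those gained in each treated list, the 10 highest shared with time 0 in HS and W10min, up to 4 members of each list with the highest fold in HS and in W10min, and 12 loci (HSFA1D, HSFA2, WIND1 to WIND4, ESR1, PLT3, PLT5, PLT7, ERF109 and ERF115). Fewer were named, and others only where said. Steps were tested on simulated data: 100% of 2000 simulated peaks were rebuilt from split rows, a list holding 30% copied peaks gave an excess of 29.4%, and of lists of 20 genes simulated at 5 times the odds 77% passed an unadjusted 0.05, against 1.5% of lists at chance.

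Alternatives set in advance were reciprocal overlap of 50%, midpoints within 200 bp, peaks at or above the median fold, a q of at most 1e-05, equal numbers of peaks, both time 0 lists as control, and leaving out genes with a peak in all 6 lists. A q of at most 0.05, promoter rows only, unmerged intervals and leaving out the dense chromosome 2 windows were added after seeing the data. Those windows are stretches of 50 kb covered for at least 10% in every list. The planned count of heat shock elements, the gene with the nearest transcription start, a shorter promoter and centromere coordinates were not run, since they need a genome sequence or a stranded annotation, which were not used here. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.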

Results

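Binding of HSFA1d was mapped in whole Arabidopsis thaliana seedlings, 2 weeks old, by chromatin immunoprecipitation and sequencing. HSFA1d is one of the class A1 heat shock factors, transcription factors that switch on chaperone genes when proteins unfold. The plants, of mixed Col-0 and Ws background, carried HSFA1d fused to GFP under the HSFA1d promoter, and the fusion was precipitated with an antibody against GFP. The heat series held an untreated time 0 (HT0) and 30 min at 37 °C (HS), each with 3 ChIP and 3 input samples of about 60 seedlings. The wounding series held an untreated time 0 (WT0) and 10 min (W10min), 3 h (W3h) and 24 h (W24h) after repeated cuts with a razor blade, each with 1 ChIP and 1 input sample. The deposited data used here are 6 lists of annotated peaks, 1 per condition, made from concatenated reads, so no value below has a spread between replicates. The labels give a floor of 10 M mapped reads for every library, and the depth is otherwise unknown.

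The HS list was the longest, with 2103 peaks, and HT0 held 1336. WT0 and W10min held 1483 and 1445 peaks, W3h held 626 and W24h held 509. Protein-coding genes with at least 1 peak, in the gene or its promoter, numbered 853 in HT0, 2145 in HS, 1948 in WT0, 1949 in W10min, 700 in W3h and 402 in W24h. Promoters were touched by 82.3% of the WT0 peaks, 80.3% of the W10min peaks and 70.1% of the HS peaks, against 54.3% in HT0, 66.6% in W3h and 44.6% in W24h. Transposable element genes were touched by 40.4% of the HT0 peaks and 44.4% of the W24h peaks, against 7.22% in WT0. Many listed peaks were weak. A q of at most 0.05 was reached by 701 peaks in HT0, 1111 in HS, 758 in WT0, 807 in W10min, 385 in W3h and 284 in W24h.

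**Figure D1:**
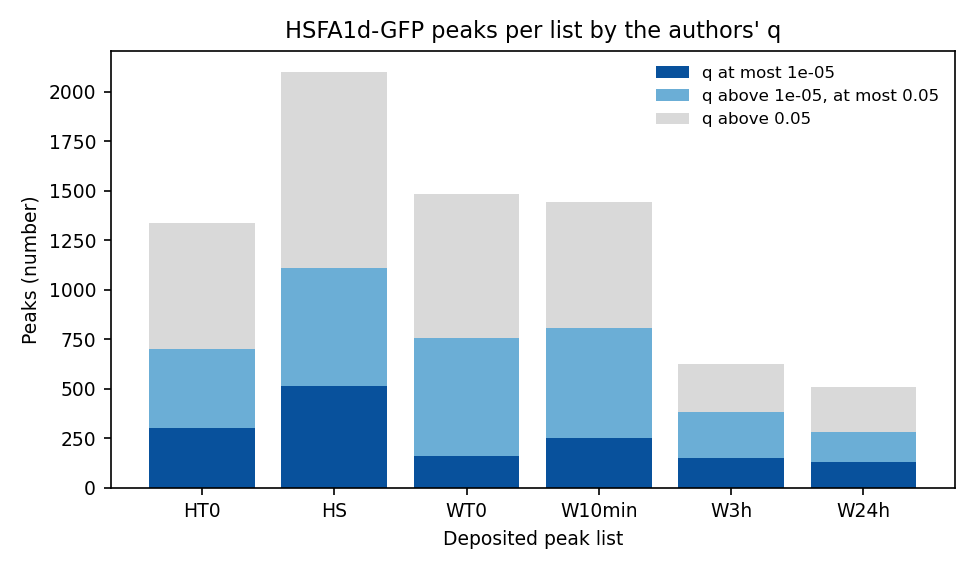
Stacked bars give the number of peaks (vertical axis) in each of the 6 deposited lists (horizontal axis), split by the authors' q value. The HS bar reaches 2103 peaks, of which 516 have a q of at most 1e-05, and the W24h bar reaches 509, of which 129 do.

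The first comparison asked where HSFA1d was found after heat. Genes of the small heat shock proteins, which hold unfolding proteins in a soluble state, had a peak in HS for 17 of the 19 listed members and in HT0 for 0. HSP17.8 (AT1G07400) carried a peak at chromosome 1, 2274520 to 2275577, over promoter and gene with a fold enrichment of 5.30, and HSP17.6II (AT5G12020) and HSP17.6A (AT5G12030) shared a peak of 5.26-fold at chromosome 5, 3883795 to 3885311. Fold enrichment is the authors' own value for each peak and ranks peaks only within its list. HSP15.4 and HSP21.7, the members with no peak, were named after their values were seen.

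The larger chaperones followed the same order. In the list of HSP90, HSP100 and HSP60 chaperones, ATP-driven folding and disaggregating machines, 15 of 17 members had a peak in HS and 4 in HT0. HSP90.1 (AT5G52640) had a fold of 5.35 at chromosome 5, 21351729 to 21353142. Among 18 members of the HSP70 family, 12 had a peak in HS and 3 in HT0, with HSP70 (AT3G12580) at 5.55-fold on chromosome 3, 3992947 to 3994567. Co-chaperones, which load and regulate HSP70 and HSP90, had a peak for 13 of 18 members in HS and 1 in HT0. HOP3, which bridges HSP70 and HSP90, stood at 5.26-fold, the peptidyl-prolyl isomerases ROF1 and ROF2 at 5.21-fold and 5.11-fold, and FES1A, an HSP70 partner, at 4.96-fold. Other heat and oxidative stress genes had a peak for 10 of 17 members in HS and 2 in HT0. They included the drought and heat transcription factor DREB2A (4.52-fold), the coactivator MBF1C (4.42-fold), the catalase CAT2 (3.49-fold) and the ascorbate peroxidase APX1 (3.34-fold). The peaks of CAT2 and APX1 met an HT0 peak, and those of DREB2A and MBF1C met none.

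Genes gained in HS, meaning with a peak in HS and none in HT0, numbered 1652, and 360 genes with an HT0 peak had none in HS. Members gained were 17 of 19 small heat shock protein genes (adjusted p = 2.41e-17 in a two-sided Fisher's exact test), 11 of 13 HSP90, HSP100 and HSP60 genes free of an HT0 peak (exact test, adjusted p = 1.0e-10), 12 of 17 co-chaperones (exact test, adjusted p = 2.74e-10), 9 of 15 HSP70 genes (exact test, adjusted p = 6.72e-07) and 8 of 15 other heat and oxidative stress genes (exact test, adjusted p = 1.06e-05). These tests compare lists, and neighbouring genes can share a peak: the HSP90.1 peak was also annotated to AT5G52620 and MEF1. Heat shock factor genes did not pass, with 4 of 17 gained (exact test, adjusted p = 0.0644), nor did early wound genes with 4 of 18 (exact test, adjusted p = 0.0742) or jasmonate genes with 3 of 25 (exact test, adjusted p = 0.331).

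The peak with the highest fold of the HS list, 5.60, lay over the promoter and gene of HSFA2 (AT2G26150) at chromosome 2, 11135070 to 11136537. HSFA2 encodes a heat shock factor that prolongs the heat response, and the locus had a peak in all 6 lists. Among other heat shock factors, HSFB2B (5.06-fold) met an HT0 peak, whereas the peaks of HSFA7A (4.72-fold) and HSFA7B (3.39-fold) met none. Further strong HS peaks that met an HT0 peak belonged to the cytosolic chaperones HSC70-3 (5.50-fold), HSP90.2 (5.40-fold) and HSC70-1 (5.30-fold), and to SOB3, an AT-hook protein of seedling growth (5.35-fold), and PIF4, a growth regulator of warm temperature (5.16-fold). The locus of HSFA1D itself (AT1G32330) had a peak in all 6 lists, where the line carries an added copy of that gene.

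Of the 2103 HS peaks, 694 (33.0%) met an HT0 peak by at least 1 bp, against a mean of 0.705% when peaks were placed at random on their chromosomes (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The other 1409 HS peaks met none, and 673 of the 1336 HT0 peaks met no HS peak. Among 358 HS peaks with a q of at most 1e-05 outside dense windows of chromosome 2 described further on, 282 (78.8%) met no HT0 peak, a setting chosen after seeing the data.

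**Figure D2:**
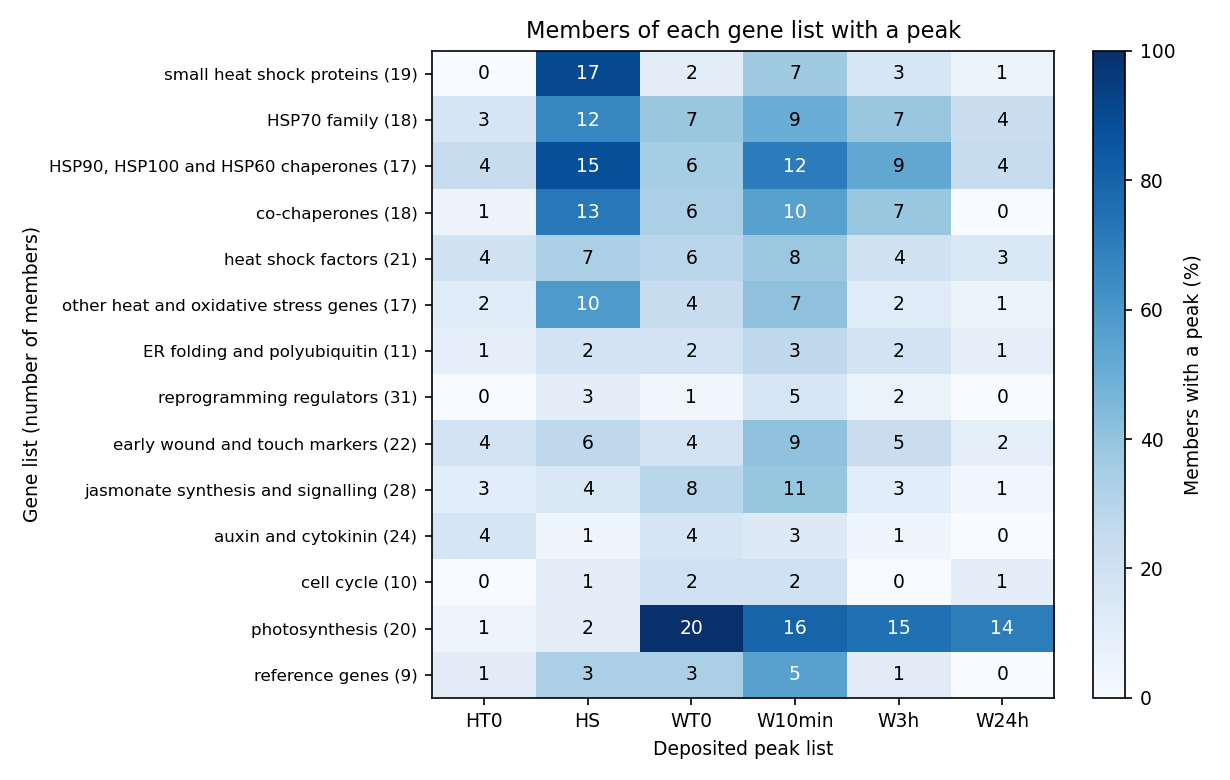
Each cell gives the number of members of a gene list (rows, with the list size in brackets) that have a peak in each deposited list (columns), shaded by the percent of members. Small heat shock proteins go from 0 in HT0 to 17 in HS and 7 in W10min, and photosynthesis genes from 1 in HT0 to 20 in WT0.

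The wounding series asked whether cutting brings HSFA1d to its sites and for how long. At 10 min the strongest peaks lay at chaperone genes and HSFA2, all with a peak that met a WT0 peak: HSC70-1 (AT5G02500), with the highest fold of the list, on chromosome 5, 556241 to 556785, HSP90.3 and HSP90.4 on a shared peak of 7.56-fold, HSP90.2 at 7.29-fold, HSFA2 at 7.22-fold and HSC70-3 at 7.16-fold. The peak of Cpn60beta2, a chloroplast chaperonin subunit, stood at 7.29-fold and also touched ECT2. Taking the chaperone and heat shock factor lists together, 46 of 93 members had a peak in W10min and 27 in WT0. In 20 members the peak was in W10min alone and in 1 in WT0 alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 3.15e-04). None of the 14 lists passed alone in this test, the lowest p being that of the HSP90, HSP100 and HSP60 list, with 6 members in W10min alone and 0 in WT0 alone (exact test, adjusted p = 0.234). Coding genes with a peak were as many, 1949 in W10min and 1948 in WT0. Peaks at a q of at most 1e-05 outside the dense chromosome 2 windows numbered 183 in W10min and 90 in WT0. Inside those windows the median fold was 4.39 and 3.53, so stronger enrichment throughout the W10min list was not told apart from wounding.

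Among genes gained at 10 min, AT5G56020 came first, but on the HSP90.3 and HSP90.4 peak, which met a WT0 peak. Organelle chaperonins came next. Cpn60beta3 (AT5G56500) carried a 5.54-fold peak over promoter and gene at chromosome 5, 22873451 to 22873795, followed by the chaperonin CPN10 (4.79-fold), the segregase CDC48 (4.46-fold), the chaperonin CPN20 (3.85-fold) and SK18 (3.78-fold), none of which met a WT0 peak. The HSP90, HSP100 and HSP60 list gained 6 of 11 free members (two-sided Fisher's exact test, adjusted p = 3.1e-05), the co-chaperones 5 of 12 (exact test, adjusted p = 6.56e-04), the small heat shock proteins 5 of 17 (exact test, adjusted p = 0.00353) and other heat and oxidative stress genes 4 of 13 (exact test, adjusted p = 0.00944). Gained members included AHA1-like (3.71-fold), an HSP90 activator, J2 (3.31-fold), an HSP40 protein, HSP17.4B (2.09-fold), HSP17.8 (1.96-fold), DREB2A (2.90-fold) and MBF1C (2.63-fold). The HSP70 family gained 2 of 11 members (exact test, adjusted p = 0.187) and heat shock factors 2 of 15 (exact test, adjusted p = 0.249). For small heat shock proteins the call was lost at a q of at most 1e-05 and with equal numbers of peaks (exact test, adjusted p = 0.343 and 0.0877).

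Some wound hormone genes and early wound transcription factors had a weak peak at 10 min and none at WT0, while others lost one. Jasmonate is the hormone of leaf wounding, and its list had 8 of 28 members with a peak in WT0 and 11 in W10min, 6 of the 20 free members being gained (two-sided Fisher's exact test, adjusted p = 9.96e-04). The lipoxygenase gene LOX4, of jasmonate synthesis, had a 2.03-fold peak, and JAZ1, a repressor of jasmonate signalling, a 2.57-fold peak of q 9.02e-06. An HS peak of JAZ1 lay within that W10min peak and met a peak of the untreated HT0, so the JAZ1 site was not free at both time 0 lists. Of the early wound and touch list, 9 of 22 members had a peak in W10min and 4 in WT0, with 6 of 18 gained (exact test, adjusted p = 6.31e-04). ZAT10, a zinc finger repressor, stood at 2.09-fold and ORA47, a regulator of jasmonate genes, at 2.03-fold. Set against members lost, neither list passed a test between WT0 and W10min: jasmonate genes had 6 members in W10min alone and 3 in WT0 alone (exact McNemar test, adjusted p = 0.635), early wound genes 6 and 1 (exact test, adjusted p = 0.312). With both time 0 lists as control, 4 of 18 free jasmonate genes and 4 of 15 free early wound genes were gained, and both gained calls were kept. Neither gained call held with 509 peaks taken from every list by fold (Fisher's exact test, adjusted p = 0.136 for jasmonate and 0.447 for early wound genes). Jasmonate members in WT0 and W10min numbered 4 and 5 in promoter rows only, 6 and 6 at a q of at most 0.05, and 1 and 1 at a q of at most 1e-05, so their rise depends on weak peaks and peaks within genes. Early wound members numbered 2 and 6 at a q of at most 0.05 and 0 and 0 at a q of at most 1e-05.

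At 3 h and 24 h the lists were shorter, and chaperone genes with a peak were fewer. Of the 93 chaperone and heat shock factor genes, 46 had a peak in W10min, 30 in W3h and 12 in W24h, while all coding genes with a peak went from 1949 to 700 and 402. Relative to the number expected from the length of each list, HSP70 members went from 7.04-fold in W10min to 15.2-fold in W3h and 15.2-fold in W24h. HSP90, HSP100 and HSP60 members went from 9.94-fold to 20.8-fold and 16.1-fold, and co-chaperones from 7.82-fold to 15.2-fold and 0. Small heat shock proteins went from 5.19-fold to 6.19-fold and 3.59-fold, and heat shock factors from 5.36-fold to 7.47-fold and 9.75-fold. Photosynthesis genes, a list for comparison, rose from 11.3-fold to 29.4-fold and 47.8-fold, so a rise in shorter lists is not particular to chaperone genes. Between W10min and W3h, 17 of the 93 chaperone and heat shock factor genes had a peak in W10min alone and 1 in W3h alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 0.00217). Between W3h and W24h the numbers were 19 and 1 (exact test, adjusted p = 6.01e-04). The comparison of W3h and WT0 did not pass, with 11 members in W3h alone and 8 in WT0 alone (exact test, adjusted p = 1). W24h held fewer members than WT0, with 3 in W24h alone and 18 in WT0 alone (exact test, adjusted p = 0.0223). These tests follow the length of the lists and do not show that chaperone genes lost peaks faster than other genes.

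At 3 h the HSP90, HSP100 and HSP60 list gained 4 of 11 members over WT0 (two-sided Fisher's exact test, adjusted p = 4.12e-05) and the co-chaperones 4 of 12 (exact test, adjusted p = 5.36e-05). Set against members lost, neither of these lists passed the McNemar test between WT0 and W3h, W3h being the shorter list. The HSP90, HSP100 and HSP60 list had 4 members in W3h alone and 1 in WT0 alone, the co-chaperones 4 and 3. The highest gained peak that met no WT0 peak, 3.34-fold at chromosome 5, 1217197 to 1217599, lay in promoters annotated to the zinc finger gene ZAT6 and to CYP84A4. Cpn60beta3 (2.94-fold), FIB, a plastid lipid-associated protein gene (2.89-fold), and CPN10 (2.59-fold) followed. At 24 h no list passed, the lowest adjusted p being 0.129 for the cell cycle list with 1 of 8 members gained (two-sided Fisher's exact test, unadjusted p = 0.0461). The ZAT6 and CYP84A4 promoters again led the genes gained at 24 h (2.48-fold), and the cold-regulated genes COR15A and COR15B shared a 2.32-fold peak.

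Of the wounding peaks, 516 of 1445 in W10min (35.7%), 327 of 626 in W3h (52.2%) and 225 of 509 in W24h (44.2%) met a WT0 peak, against random means of 0.968%, 1.24% and 1.36% (one-sided permutation p = 0.001 for each, the smallest possible). Gained genes numbered 1160, 291 and 150, and genes with a WT0 peak and none after wounding 1159, 1539 and 1696. Outside the dense windows and at a q of at most 1e-05, 63 of 183 W10min peaks met no WT0 peak (34.4%).

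The series is about wound-induced reprogramming, and the regulators of that process formed 1 list of 31 genes. WIND1 (AT1G78080), an AP2/ERF factor that promotes callus at wounds, had a promoter peak in HS at chromosome 1, 29361248 to 29362043, with a fold of 3.59 and a q of 7.53e-17. In W3h a promoter peak at 29361248 to 29361542 had a fold of 2.39 and a q of 2.8e-06, and in W10min a peak at 29361585 to 29361907 had a fold of 1.89 and a q of 0.0674. No WIND1 peak was listed in HT0 or W24h, and in WT0 there was only a peak within the gene, at 29364502 to 29364795, with a q of 0.603. None of the WIND1 peaks in HS, W10min or W3h met a time 0 peak.

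Other regulators had few peaks, and only that of WOX11 reached a q of at most 1e-05 among those named here. WIND2 had promoter peaks in W10min (2.03-fold, q 0.0145) and HS (1.62-fold, q 0.35), and ERF109, a jasmonate-responsive factor of root regeneration, had a peak in W10min (1.96-fold, q 0.0319). WOX11, a homeobox gene of new root formation, had a gene peak in W10min of 2.77-fold and q 3.63e-07. PLT7 had a peak in W10min with q 0.507 and PLT3 in W3h with q 0.024. WIND3, WIND4, ESR1, PLT5 and ERF115 had no peak in any list. As a group, 3 of 31 members had a peak in HS, 5 in W10min, 2 in W3h and 0 in W24h, and the gained members, 3 in HS and 4 in W10min, did not pass (two-sided Fisher's exact test, adjusted p = 0.647 and 0.129). WIND1 was not counted as gained in W10min, because its weak WT0 peak within the gene (q 0.603) counts as a peak at time 0.

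**Figure D3:**
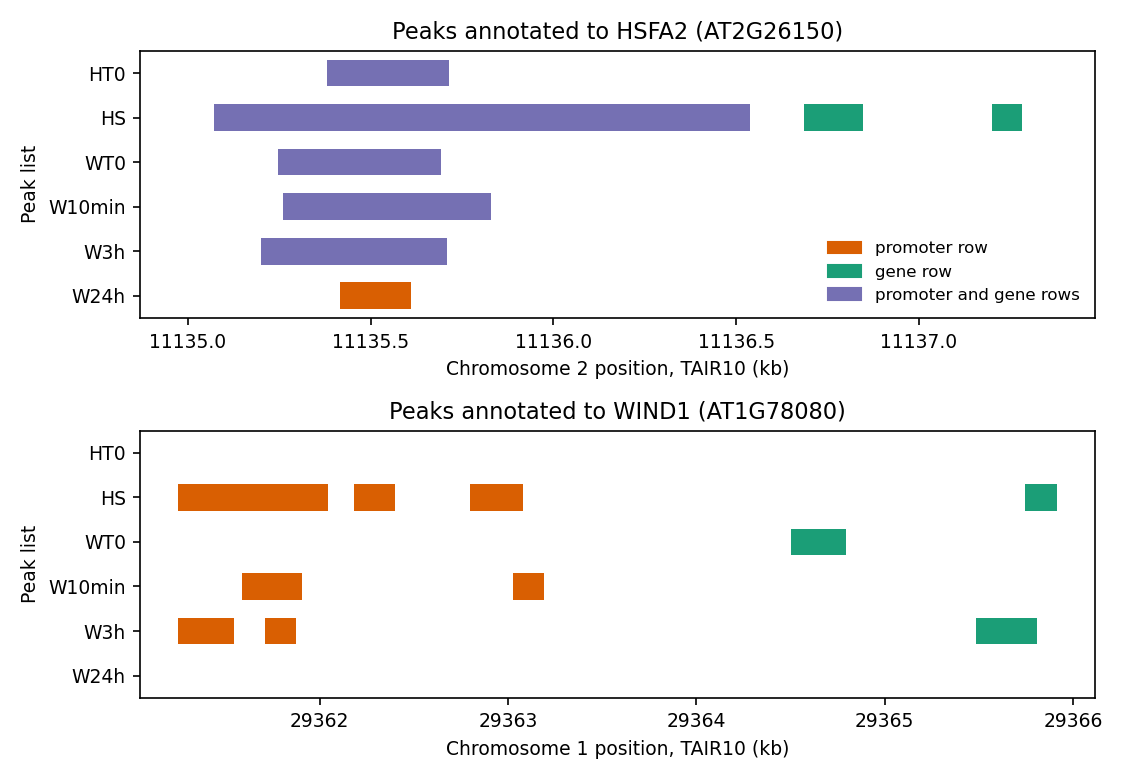
Horizontal bars are the listed peaks annotated to HSFA2 (upper panel, chromosome 2) and WIND1 (lower panel, chromosome 1) in each of the 6 lists, with TAIR10 position in kb on the horizontal axis and colour for rows in the promoter, the gene or both. HSFA2 has a peak in all 6 lists, and WIND1 promoter peaks appear in HS, W10min and W3h.

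Heat and wounding were then compared directly. Among the chaperone and heat shock factor lists taken alone, only small heat shock proteins passed: 17 members had a peak in HS and 7 in W10min, 10 of them in HS alone and 0 in W10min alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 0.00977). In W10min the members with the highest folds were HSP23.5, a mitochondrial form (3.17-fold), and HSP17.6A-CI, a cytosolic form, and both peaks met a WT0 peak. Photosynthesis genes went the other way, with 0 members in HS alone and 14 in W10min alone (exact test, adjusted p = 9.16e-04). That call was lost at a q of at most 1e-05, with 0 and 7, and in promoter rows only, with 2 and 6 (exact test, adjusted p = 0.0586 and 0.723). The heat and wounding series already differed in these genes before treatment, with 20 members in WT0 and 1 in HT0. For chaperone and heat shock factor lists together, 45 members had a peak in both, 19 in HS alone and 1 in W10min alone (exact test, adjusted p = 6.01e-04). Members with a peak in both lists included HSC70-1, HSC70-3, HSP90.2, ROF1 and HSFA2.

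Genes with no peak at either time 0 included 1297 gained in HS and 1088 gained in W10min, of which 333 were shared against 56.3 for independent lists (odds ratio 10.5, two-sided Fisher's exact test, p = 3.38e-172). Genes recur between any of these lists: genes with a peak in WT0 and none in HT0 overlapped the HS gained genes with an odds ratio of 5.62, although WT0 was untreated. Of the 183 strong W10min peaks outside the dense windows, 142 (77.6%) met an HS peak, and 213 of the 358 strong HS peaks (59.5%) met a W10min peak. Of the same 183, 120 met a peak of the untreated WT0. Strong peaks of W3h and W24h met an HS peak for 80% and 74.5%, so the share is not particular to 10 min.

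Between wounding times, 120 genes were gained in both W10min and W3h against 13.2 for independent lists (odds ratio 16.3, two-sided Fisher's exact test, adjusted p = 1.05e-82), among them Cpn60beta3 and CPN10. For W10min and W24h the number was 40 against 6.82 (odds ratio 7.87, exact test, adjusted p = 3.84e-20), and for W3h and W24h 30 against 1.71 (odds ratio 24, exact test, adjusted p = 1.66e-28), with ZAT6 and CYP84A4 in the last pair. All 3 lists were set against the same WT0, so these overlaps are not independent of it. The untreated HT0 list put in the place of a treated one gave odds ratios of 4.59 with W10min, 8.25 with W3h and 16.1 with W24h.

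Finally the untreated lists were compared, since both came from the same line without treatment. Of 1336 HT0 peaks, 478 (35.8%) met a WT0 peak, and 355 of 1483 WT0 peaks (23.9%) met an HT0 peak (random mean 0.971%, one-sided permutation p = 0.001, the smallest possible). Chaperone and heat shock factor genes had a peak for 12 of 93 members in HT0 and 27 in WT0, with 2 in HT0 alone and 17 in WT0 alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 0.00546). All coding genes with a peak numbered 853 in HT0 and 1948 in WT0, so the test does not show a difference particular to chaperone genes. HT0 also pooled 3 ChIP samples, and WT0 held 1. HSC70-1 stood at 4.61-fold in WT0 and 1.75-fold in HT0, and HSP90.2 at 4.12-fold and 1.72-fold, values that rank peaks within each list only. At a q of at most 1e-05 the difference of members between the lists was 6 and no longer passed (exact test, adjusted p = 0.469).

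Photosynthesis and reference genes served as lists for comparison. Photosynthesis genes had a peak for all 20 members in WT0 (two-sided Fisher's exact test, adjusted p = 8.08e-22), 16 in W10min, 15 in W3h and 14 in W24h, and for 1 in HT0 and 2 in HS. They were gained for 0 members at any wounding time, since all had a WT0 peak, and for 2 of 19 in HS (exact test, adjusted p = 0.503). The antenna genes CAB1 and CAB2 shared a 3.29-fold peak in W10min and the Rubisco gene RBCS3B had one of 3.08-fold. Of 9 reference genes, 5 had a peak in W10min, including GAPC1 of glycolysis at 2.70-fold (exact test, adjusted p = 6.49e-04), and 3 in WT0 and HS. Gained were 2 of 6 reference genes in W10min and 2 of 8 in HS (exact test, adjusted p = 0.0854 and 0.187). Their odds ratio in W10min, 10.5 on few members, was above that of small heat shock proteins (8.77) and jasmonate genes (9.03). It was below that of co-chaperones (15.0) and of the HSP90, HSP100 and HSP60 list (25.3). Reference genes with a W10min peak stood at 7.82-fold over the number expected, as co-chaperones did. The W10min calls are thus not shown to be particular to stress genes.

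Parts of chromosome 2 were covered in every list. In 9 windows of 50 kb, 1 at the start of the chromosome and the others between 3.2 and 3.65 Mb, listed peaks covered 46.3% to 48.9% of the 450 kb in all 6 lists, and 0.285% or less of the 300 kb before 3.2 Mb. They held 53.2% of the covered length in HT0, 34.1% in HS, 37.9% in WT0, 37.5% in W10min, 59.5% in W3h and 66.1% in W24h. Of 135 genes with a peak in all 6 lists, 68 lay in these windows.

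**Figure D4:**
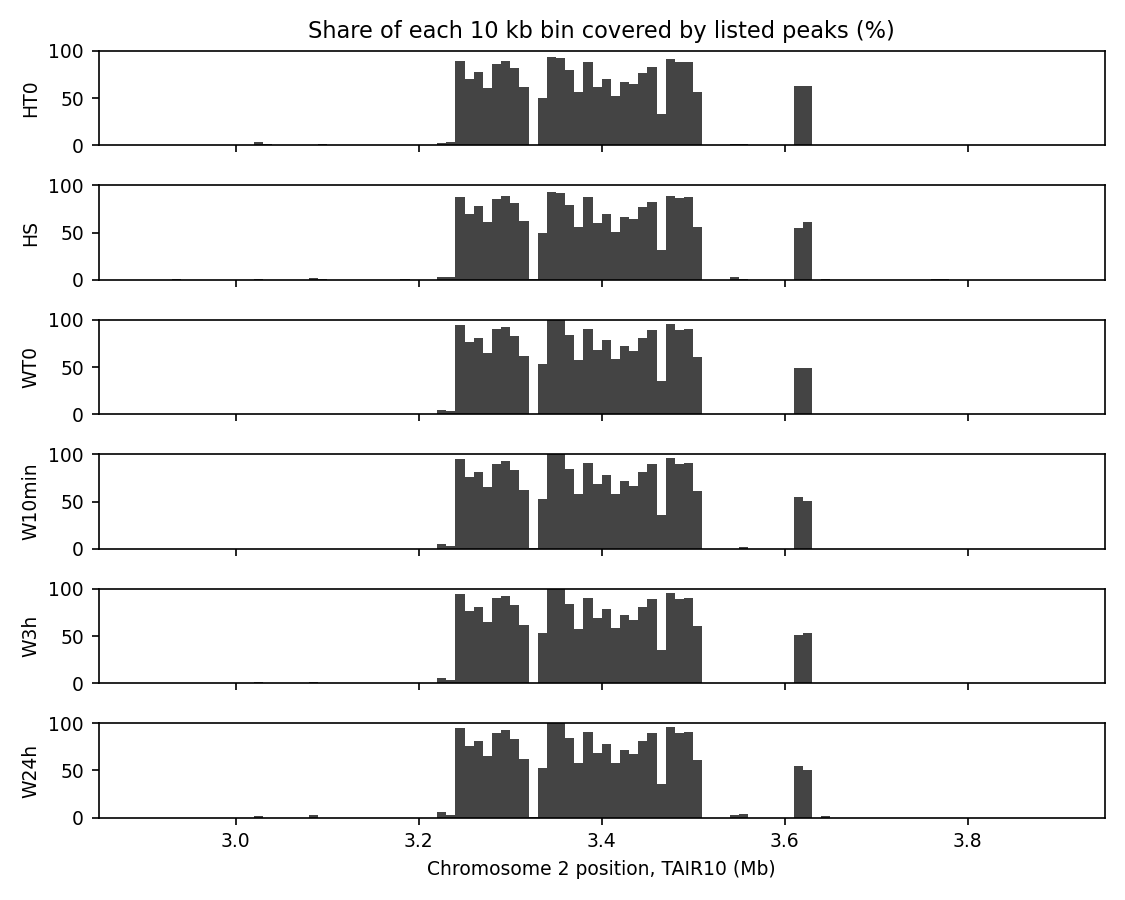
Bars give the percent of each 10 kb bin covered by listed peaks (vertical axes, 0 to 100%) along part of chromosome 2 in Mb (horizontal axis), with 1 panel per deposited list. The same stretches above 3.2 Mb are covered in all 6 lists, and the 300 kb before 3.2 Mb are covered for at most 0.285%.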

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

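The tests with a p in this part were chosen after the result was seen. Small heat shock protein genes were gained in HS far more often than in W10min: among 17 members free of a peak at both time 0 lists, 15 were gained in HS and 5 in W10min, a difference of 10 (two-sided exact McNemar test, adjusted p = 0.0146). For the chaperone and heat shock factor lists together, 38 of 64 free members were gained in HS and 19 in W10min, a difference of 19 (exact test, adjusted p = 5.72e-05). Both stand out because the gained members of the HS and W10min lists differed in a direct test. That test counts genes in 1 list each and does not show that the effects of heat and wounding differ.

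The length of the HS list is argued against as the source of the small heat shock protein difference. With 509 peaks taken from each list by fold, 13 of 18 free members were gained in HS and 2 in W10min (exact McNemar p = 9.77e-04). Such lists need not be equal in length outside the dense chromosome 2 windows. In the full lists those held 77 W10min peaks of median fold 4.39 and 213 HS peaks of median fold 1.88. Weaker enrichment throughout the W10min list stays open. Chaperone and heat shock factor members with an HS peak were put in 4 classes of HS fold. A W10min peak was found for 7 of 17 small heat shock proteins, against 11.1 expected (two-sided stratified exact p = 0.00481). The expected number takes the share of all members of each class, small heat shock proteins included. Among members free of a peak at both time 0 lists, however, it was 5 of 15 against 6.98 (exact p = 0.204). Small heat shock proteins of the 2 upper classes had a W10min peak for 4 of 5 and 3 of 3 members, and of the lower ones for 0 of 3 and 0 of 6, where others had one for 11 of 13 and 5 of 10, which a first test of the upper part alone had missed. The number of ChIP libraries pooled, 3 in HS and 1 in W10min, cannot be told apart from the treatment, because it goes with it. The treatments also differ in length, 30 against 10 min, and a biological difference between heat and wounding stays open and untested.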

How the results depend on the processing

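No paired analysis was possible because each condition has 1 list from pooled reads, so the shared replicate numbers of the labels mark nothing in these files and no replicate could be left out. The 5 peak overlaps stayed above random placement under all 8 alternatives (15.3% to 88%), the 4 overlaps of gained genes kept their call in 23 of 23 values, and the 5 lists gained in HS in 30 of 30. Over all 13 gained lists 71 of 78 values kept their call, the 7 losses all being in W10min, and tests of members between lists kept 65 of 70. At a q of at most 1e-05 the number of lists called with a peak moved from 40 to 21, with fewer peaks to find them by. Peaks at that q numbered 304 in HT0, 516 in HS, 161 in WT0, 253 in W10min, 150 in W3h and 129 in W24h, and at a q of at most 0.05, added after seeing the data, 701, 1111, 758, 807, 385 and 284. Unmerged intervals, also added, numbered 3169 in HS, 2330 in WT0, 2380 in W10min and 1029 in W3h, since split peaks then count more than once. WT0 held 6 more chaperone and heat shock factor genes than HT0 at a q of at most 1e-05, no longer past the threshold, against 15 in full lists. Called lists fell to 0 members at a q of at most 1e-05 for small heat shock proteins in W3h, the HSP70 family, heat shock factors, and auxin and cytokinin genes in HT0, HSP90, HSP100 and HSP60 chaperones in HT0 and W24h, co-chaperones and reference genes in WT0, and early wound genes in HT0, W10min and W3h and among those gained in W10min. The same fall to 0 came with equal numbers of peaks for HSP70, HSP90 and early wound genes in HT0, with a q of at most 0.05 for early wound genes in HT0, and without genes listed in all 6 for heat shock factors in W24h. Such lists held few members to begin with or only weak peaks. Not run were the nearest transcription start, a shorter promoter, the centromere filter and the alternatives of the heat shock element count, which need a genome sequence or stranded annotation. Of 240 alternative values of lists with a peak, 188 kept their call.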

Other observations

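Several groups moved little. Of 11 genes of endoplasmic reticulum folding and polyubiquitin, 2 had a peak in HS and 3 in W10min, with UBQ10 at 2.41-fold and 2.03-fold (two-sided Fisher's exact test of gained members, adjusted p = 0.225 and 0.147). Auxin and cytokinin genes had a peak for 4 of 24 members in HT0, 1 in HS, 4 in WT0 and 3 in W10min, where the cytokinin oxidase CKX5 stood at 2.16-fold, and 0 members were gained in HS or W10min (exact test, adjusted p = 0.886 and 1). In the untreated HT0 they passed, at 5.36-fold over the number expected (exact test, adjusted p = 0.0136). Between HT0 and HS, 3 members had a peak in HT0 alone and 0 in HS alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 0.469). Of 10 cell cycle genes only KNOLLE, a syntaxin of cell plate formation, had an HS peak (2.26-fold), and it had one in W10min (1.96-fold). It was the only member gained in each (exact test, adjusted p = 0.68 and 0.484). Early wound genes were found in HS too, for 6 of 22 members, led by the zinc finger gene ZAT12 at 2.90-fold, but also in the untreated HT0 for 4, with 4 in HS alone and 2 in HT0 alone (two-sided exact McNemar test, chosen after seeing the data, adjusted p = 0.938).

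Tests in the next paragraphs were chosen after the result was seen. For the peaks at photosynthesis genes in the wounding lists, binding brought about by wounding is argued against, since all 20 members had a peak in the untreated WT0 list and 16 in W10min. List length is too, since with 509 peaks per list 14 members had a WT0 peak and 0 an HT0 peak (two-sided exact McNemar p = 1.22e-04). At a q of at most 1e-05 the numbers were 5 and 0 and the call was lost (exact test, adjusted p = 0.469), though WT0 was then the shorter list, with 161 peaks against 304. Outside the dense chromosome 2 windows these were 90 and 126. In the full lists those windows held 78 WT0 and 198 HT0 peaks, so lists of 509 peaks need not be equal in length elsewhere. Background over the bodies of highly transcribed genes may be a source: of members with a WT0 peak, 45% of the 20 photosynthesis genes had rows in the gene only, against 3.70% of the 27 chaperone and heat shock factor genes (two-sided Fisher's exact p = 9.11e-04), while any row in the gene on the highest peak was as common in both (85% and 81.5%, exact p = 1). Binding within genes would give the same, transcription and peak strength were not compared, and no list from plants without GFP was used here, so the source stays open.

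The dense windows of chromosome 2 were covered in every list. Peaks that appear with treatment do not explain them, since windows chosen by each treated list alone were the same 9, and no treated list covered more of them than its time 0 by over 0.396 percentage points. Reads of a sequence with many copies placed there, such as mitochondrial DNA, of which this arm holds a nuclear copy, are a candidate source. When windows were chosen by 1 list alone, 88.4% to 91.2% of the bases covered in any of the other 5 lists were covered in all 5. The window at the start of the chromosome lies apart from those between 3.2 and 3.65 Mb, so the same source need not hold for both. Median folds inside the windows were above those outside in every list (3.53 against 1.82 in WT0, 1.88 against 1.75 in HS). Copies read alike in ChIP and input would not give that. Binding that is there in every condition would be shared in the same way. In the 6 lists, 77 to 213 peaks covered 208 to 220 kb of these windows, while median peak widths of the lists were 128 to 236.5 bp. Stretches so long argue against binding at separate short sites. Broad binding in every condition was not tested, so the source otherwise stays open.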
